A study of Mus musculus with 6 samples.

How the data were processed

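RNA was sequenced from primary microglia, the resident macrophages of the brain, of 8-week-old C57BL/6J mice. The 6 libraries fall into 2 groups of 3: Mir137 knockout (gKO) and wild type (gWT), as given by the sample labels. The labels do not say that the 3 libraries of a genotype came from separate animals, and the study's design text mentions 4 mice without mapping them to libraries. The p-values given here therefore measure the spread between these libraries, which may be technical.

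The authors deposited one table of expected counts per gene symbol for the 6 libraries and lists of genes higher and lower in gKO. The submitters' processing notes name STAR 2.7.9a, RSEM, DESeq2 and the genome builds GRCm38 and mm10, with no role or order. The gene annotation and the strand setting are not given in the sources used here. The deposited counts were estimated per gene and not normalized, since the totals differ between libraries and some values are not whole numbers. The share of such values was 2.64% to 2.83% in the gKO libraries and 3.35% to 3.65% in the gWT libraries. The reason for this difference between the groups was not tested. In the authors' deposited lists, per the file headers, each gene has a mean of normalized counts (a signal), a log2 fold change of gKO over gWT, its standard error and a Wald-type statistic (both scores without a fixed range), a p-value and an adjusted p-value. The listed genes all have an adjusted p of at most 0.0500 and an absolute log2 fold change of at least 1.00.

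The total of the deposited counts was 17652976, 14603884 and 14920304 in gKO replicates 1, 2 and 3, and 16328561, 17306422 and 16867949 in the gWT replicates. Every count column was mapped to a sample by its name, which gives the genotype and replicate number. The 24411 symbols were matched to GENCODE M21 and RefSeq tables of GRCm38 for identifiers, lengths and coordinates, 23365 by name and 666 by synonym. A further 380 had no match, of which 12 had been turned into dates by spreadsheet software.

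Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3: TMM normalization, the default filter on low counts, and a quasi-likelihood test with robust dispersion on genotype alone. The Benjamini-Hochberg method adjusted p over the 13403 genes that passed the filter, and an adjusted p under 0.05 called a gene. Standard errors (SE) are the absolute log2 fold change divided by the square root of the F statistic. Levels are CPM values scaled by TMM, as mean ± SD over 3 libraries. Gene lists with at least 5 tested members were compared with all other genes by camera of limma 3.58.1, on log CPM with a prior count of 2 and an inter-gene correlation of 0.01. These lists cover microglial states and functions, reported miR-137 targets, and markers of other brain and blood cells. Of 37 lists, 34 had enough tested members. For each list the number of called members is also given with p adjusted over the list alone. Genomic coordinates are 1-based on GRCm38.

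For the microRNA's target sites, 3′ UTRs of the longest annotated transcripts were searched for AGCAATA, the complement of bases 2 to 8 of the mature microRNA. Median log2 fold changes of genes with and without a site were compared within 10 bins of UTR length, and the difference was ranked among 180 rearrangements of the same 7 bases that hold no CG.

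The groups, the test, the gene lists, the rule for naming genes and the alternative settings were chosen before the data were examined, except where the text says otherwise. The rule named the 12 largest rises and 12 largest falls among called genes with non-overlapping groups and a mean of at least 1 CPM, leaving out predicted genes, pseudogenes and ribosomal or histone copies. It also named up to 4 called members of each list, or up to 2 members with the smallest p where none was called, a few fixed genes, and the 3 most abundant called genes in each direction. The text gives a part of the 90 genes so chosen, 45 of them past the threshold. The alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom with and without sample weights, other filters, a fold-change minimum, the replicate number as a block, each library left out, an estimated inter-gene correlation, and fry. Removing each library's trend with transcript length was added after the data were examined.

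The test was checked on counts simulated for the comparison of gKO with gWT, in 10 draws of a median of 13053 genes with 200 changed genes each. It recovered 3.88% of genes changed 1.5-fold, 36.0% of those changed 2-fold and 77.7% of those changed 4-fold, and 6.92% of its 838 calls were false. The test therefore missed most of the simulated changes of 1.5-fold and of 2-fold. The simulation did not separate depth, the number of libraries and the spread between libraries as reasons for this. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom from 6.49 upward, so none was counted as a duplicate.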

Results

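Gene expression was measured by RNA sequencing in microglia from adult mice that lacked Mir137 in the germline (gKO, n = 3 libraries) or were wild type (gWT, n = 3 libraries). The comparison asks how the loss of this microRNA changes the microglial transcriptome. The libraries held 14603884 to 17652976 counts. Between 13832 and 14090 genes had a count above 0 in the gKO libraries, and between 15012 and 15277 in the gWT libraries. gKO replicate 3 stood apart from the other 5 libraries. It lay at 91.5 on the first principal component, which held 39.0% of the variance, whereas the others lay between -37.7 and -3.45. Across genes, its deviation from the mean fell with transcript length (Spearman rho = -0.50, genes not being independent replicates), against -0.04 to 0.30 in the others.

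The targeted gene, Mir137 (chromosome 3, 118433857 to 118433929), had 0 counts in each of the 6 libraries. A microRNA precursor is poorly captured by this kind of library, so this gene checks nothing about the labels. Of its neighbours, Ptbp2 (chromosome 3, 119718742 to 119784466), a splicing repressor, had 34.8 ± 8.95 CPM in gKO and 17.7 ± 1.94 CPM in gWT (SD, n = 3 each). Its log2 fold change of 0.97 (SE 0.23) had an edgeR adjusted p of 0.149 over all genes, so it was not called. Adjusted over the fixed genes Ptbp2, Dpyd and Jdp2 alone, which are not one of the gene lists, its edgeR p was 0.00368. Dpyd (chromosome 3, 118562129 to 119432924), an enzyme of pyrimidine breakdown, had 0, 13 and 2 counts in gKO and 38, 22 and 19 counts in gWT, with an edgeR adjusted p of 0.598. Jdp2 (chromosome 12, 85599027 to 85639878), a repressor of the AP-1 family fixed as a gene of interest, rose from 13.8 ± 1.59 to 37.0 ± 6.17 CPM (SD, n = 3 each; log2 fold change 1.42, SE 0.20, edgeR adjusted p = 0.0246). Its 920-base 3′ UTR holds 1 AGCAATA site, at base 673. Jdp2 was called with all 6 libraries and without gKO replicate 3, and its edgeR adjusted p lay between 0.0800 and 0.234 without any other single library.

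By camera, 10 of 34 fixed gene lists were called, among them the immediate-early and NF-kB lists as higher and the vascular list as lower in gKO, and 0 of them were called with an estimated correlation. The largest rises were in Cxcl2, a neutrophil-attracting chemokine, at 4.68-fold, and in the cytokine gene Tnf, at 4.23-fold. Tnf had 117 ± 21.7 CPM in gKO and 27.7 ± 5.52 CPM in gWT (SD, n = 3 each). Cxcl2 had 15.5, 20.4 and 40.5 CPM in gKO replicates 1, 2 and 3, the highest value being that of replicate 3. Its level in gWT was 5.43 ± 0.28 CPM (SD, n = 3, edgeR adjusted p = 0.0437). Xist, the RNA that silences the X chromosome, was nearly absent from gKO. The matrix gene Eln, which encodes elastin, fell from 984 ± 162 to 330 ± 93.1 CPM (SD, n = 3 each). In all, 53 genes were higher and 31 lower in gKO among 13403 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 1460 had an unadjusted p under 0.05. The groups did not overlap in 2849 genes, 21.3% of those tested, where chance gives 10%. The counts depended on single libraries: without gKO replicate 3, 551 genes were higher and 528 lower, including all 84 of the original calls. Without gKO replicate 1 or 2, 4 genes (Nfkbiz, Nfkbid, Nr4a1 and Atf3) were higher and Xist was lower, and without any 1 gWT library edgeR called 0 genes, with 729 to 921 at an unadjusted p under 0.05.

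**Figure D1:**
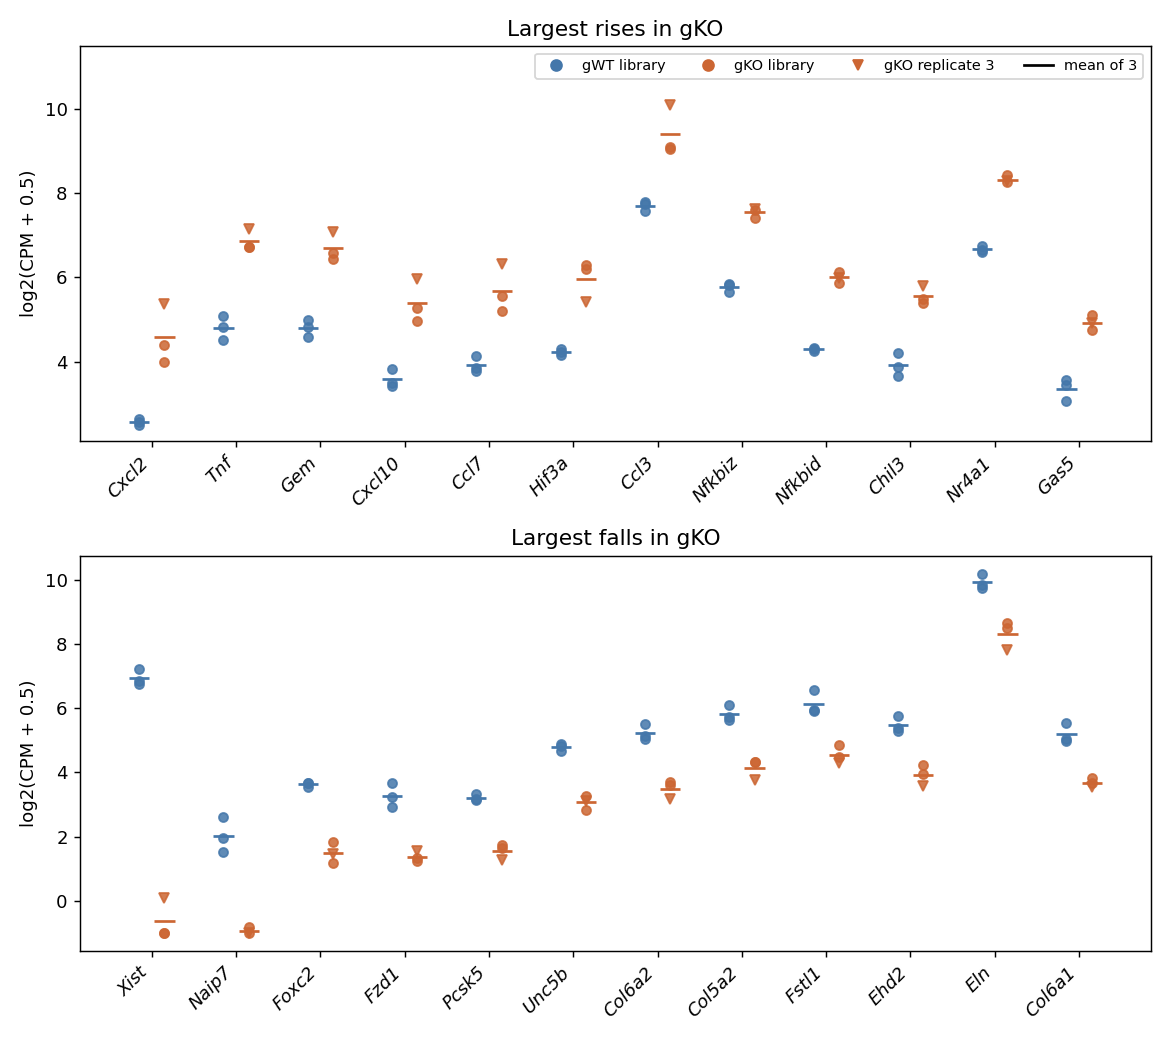
Expression of the 12 genes with the largest rises (top) and the 12 with the largest falls (bottom) in gKO, as log2(CPM + 0.5) on the vertical axis for each library. Blue points are gWT and orange points gKO libraries, triangles mark gKO replicate 3, and short lines are means of 3 libraries; the groups do not overlap for any of these genes, and Xist and Naip7 lie near the floor in gKO.

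Immediate-early genes, which respond within minutes to stimulation or cell handling, formed the list with the smallest camera p. Of 31 tested members, 12 rose and 0 fell (18 and 0 when adjusted over the list alone), with a median log2 fold change of 0.84. The nuclear receptor Nr4a1 rose from 101 ± 5.09 to 319 ± 19.4 CPM (log2 fold change 1.66, SE 0.12, edgeR adjusted p = 0.00246), and the stress-induced factor Atf3 rose from 239 ± 9.20 to 641 ± 26.3 CPM (log2 fold change 1.42, SE 0.12, edgeR adjusted p = 0.00431; SD, n = 3 for each mean). The phosphatase gene Dusp1 (log2 fold change 1.24) and the AP-1 gene Fosb (1.53) rose as well. The 3 most abundant rising genes, Jund (0.84), Fos (1.07) and Egr1 (1.12), are transcription factors of the same early response. The 4 heat shock members of the list were not called by edgeR, with log2 fold changes of -0.01 for Hspa1a, -0.17 for Hspa1b, 0.08 for Hsp90aa1 and 0.22 for Dnajb1. The camera adjusted p was 1.33e-18, and the adjusted p = 0.0705 with an estimated correlation. In the overlapping list of AP-1 and partner factors, 5 of 22 rose (6 adjusted over the list alone), with a median of 0.19, camera adjusted p = 0.000836 and adjusted p = 0.161 with an estimated correlation. Without gKO replicate 3, 20 members of the immediate-early list and 8 of the AP-1 list rose, and without any other single library edgeR called at most 5 genes in the whole table.

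Of 30 tested cytokine and NF-kB genes, 8 rose and 0 fell (14 higher and 1 lower adjusted over the list alone), with a median log2 fold change of 0.57. Ccl3, a chemokine of activated macrophages, rose from 208 ± 15.0 to 719 ± 324 CPM (SD, n = 3 each; log2 fold change 1.79, SE 0.28, edgeR adjusted p = 0.0385). Inhibitors and modulators of NF-kB rose with the cytokines: Nfkbiz (log2 fold change 1.79, SE 0.13), Nfkbid (1.73, SE 0.15) and Nfkbia (1.21, SE 0.13). The monocyte attractant Ccl7 (1.86, SE 0.29) rose too. The subunit and receptor genes in the list were not called, with log2 fold changes of -0.08 for Nfkb1, -0.13 for Relb and 0.02 for Tlr2. The camera adjusted p was 1.79e-08, and the adjusted p = 0.176 with an estimated correlation. Leaving out gKO replicate 3, the median dropped to 0.21, while 13 rose and 1 fell. The median was 0.74 to 0.95 without any other single library, where edgeR called at most 5 genes in all.

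Type I interferon response genes went the other way as a list. Cxcl10, an interferon-induced chemokine also driven by NF-kB, rose from 11.6 ± 1.81 to 43.4 ± 16.0 CPM (SD, n = 3 each; log2 fold change 1.90, edgeR adjusted p = 0.0326). EdgeR called 0 of the other 33 tested members, with 5 of the 34 at an unadjusted p under 0.05, while DESeq2 called 2 lower and voom with quality weights 1 lower. In edgeR, 29 of the 34 had a negative fold change, with a median of -0.33. Adjusted over the list alone, 1 was higher and 3 lower, among them Usp18 (log2 fold change -2.33) and Oasl2 (-1.10), picked out after their values were seen. The camera adjusted p was 0.00104, and the adjusted p = 0.185 with an estimated correlation. In the fit without gKO replicate 3, 5 members were lower and 1 higher.

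All 15 tested neutrophil genes had a positive fold change, with a median of 1.11; 2 rose (8 adjusted over the list alone), namely the granule genes Ltf, from 47.8 ± 4.89 to 105 ± 11.1 CPM (edgeR adjusted p = 0.0221), and Mmp9, from 30.9 ± 3.14 to 60.5 ± 7.05 CPM (edgeR adjusted p = 0.0427; SD, n = 3 for each mean). The camera adjusted p was 8.43e-09, and the adjusted p = 0.161 with an estimated correlation. In the monocyte list, 3 of 17 rose (3 adjusted over the list alone), with a median of 0.45: Nr4a1, Chil3 (log2 fold change 1.67, SE 0.21) and Hp (1.15, SE 0.18). The summed level of the monocyte list was 905 CPM in gKO and 907 CPM in gWT. Its camera adjusted p was 0.00173, and the adjusted p = 0.161 with an estimated correlation. Without gKO replicate 3, 7 neutrophil genes rose, their median was 0.58, and the monocyte list was no longer called (median 0.26, camera adjusted p = 0.0896).

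Of 21 tested endothelial and mural genes, 2 fell and 0 rose (14 and 0 adjusted over the list alone), and 19 had a negative fold change, with a median of -0.79. The tight-junction gene Cldn5 fell from 259 ± 27.9 to 127 ± 12.8 CPM (log2 fold change -1.03, SE 0.14, edgeR adjusted p = 0.0246). Acta2, the actin of smooth muscle and mural cells, fell from 54.2 ± 9.18 to 21.1 ± 3.51 CPM (log2 fold change -1.36, SE 0.20, edgeR adjusted p = 0.0312; SD, n = 3 for each mean). The camera adjusted p was 8.43e-09, and the adjusted p = 0.185 with an estimated correlation. Besides Xist, Naip7 and Eln, the 12 largest falls were Foxc2 (log2 fold change -2.32, SE 0.30), Fzd1 (-2.17, SE 0.35), Pcsk5 (-1.84, SE 0.31), Unc5b (-1.78, SE 0.21), Col6a2 (-1.77, SE 0.22), Col5a2 (-1.72, SE 0.22), Fstl1 (-1.63, SE 0.24), Ehd2 (-1.58, SE 0.23) and Col6a1 (-1.57, SE 0.22). Collagen genes were counted as a family after these values were seen: 6 of 32 tested fell, 29 were negative, and the median was -1.16. The fixed list of adhesion, cytoskeleton and matrix genes had 0 falls among 34 tested by edgeR (4 without gKO replicate 3), 0 by DESeq2 and 2 by voom with quality weights, and 11 genes of either sign at an unadjusted p under 0.05 in edgeR. Without gKO replicate 3, 13 of the vascular list fell, and without any other single library edgeR called at most 5 genes in all.

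Astrocyte markers were lower as a list, with 16 of 17 negative, a median of -0.60 and 0 called by edgeR (7 at an unadjusted p under 0.05; 3 lower adjusted over the list alone, the gap junction gene Gja1 first at -1.07). The camera adjusted p was 5.72e-05, and the adjusted p = 0.185 with an estimated correlation. All 10 tested markers of ependyma and choroid plexus were negative, with a median of -0.80 and 0 called by edgeR (3 at an unadjusted p under 0.05, 1 lower adjusted over the list alone), a camera adjusted p of 0.00792 and an adjusted p = 0.662 with an estimated correlation. Of 6 erythroid genes, 5 were negative, with a median of -0.59 and 0 called by edgeR (1 at an unadjusted p under 0.05, 1 lower adjusted over the list alone), a camera adjusted p of 0.0180 and an adjusted p = 0.313 with an estimated correlation. The ependymal list lost its call without gKO replicate 2 (camera adjusted p = 0.419) or gWT replicate 1 (0.182), with medians of -0.42 and -0.21, and the erythroid list without gKO replicate 1 (0.0588) or gKO replicate 2 (neither under 0.05). The erythroid median was -1.64 without gKO replicate 3, that library holding 142 CPM of these genes in sum against 52.2 and 49.4 CPM in the other gKO libraries. The astrocyte median was -0.39 without gKO replicate 1. The 15 tested oligodendrocyte markers had a median of 0.21 and were not called as a list by camera (adjusted p = 0.217), nor were neurons (median -0.19, 0 of 17 called), oligodendrocyte precursors (-0.44, 0 of 9) or border macrophages (0.16, 0 of 17), where edgeR had 0, 1 and 3 genes at an unadjusted p under 0.05. DESeq2 called 1 lower member in each of the astrocyte, ependymal, erythroid and precursor lists, voom 1 lower astrocyte gene, and voom with quality weights 1 lower astrocyte, erythroid and border macrophage gene each. Leaving out gKO replicate 3, edgeR called 2 lower astrocyte, ependymal and erythroid genes each, 1 lower precursor gene, and 1 higher and 3 lower border macrophage genes. Only 3 T or NK cell genes and 3 B cell genes passed the filter, and 0 genes of the mitochondrial genome, so these lists were not tested.

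Xist (chromosome X, 103460366 to 103483254) had 0, 0 and 8 counts in gKO against 2519, 2000 and 1830 counts in gWT, a ratio of 741 (95% exact interval 376 to 1718, counting error only). It overlaps the antisense gene Tsix, from which its reads cannot be told apart without a stated strand setting. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were present in all 6 libraries, Ddx3y at 98.6 ± 9.90 CPM in gKO and 74.6 ± 2.49 CPM in gWT (SD, n = 3 each; log2 fold change 0.40, edgeR adjusted p = 0.315). Naip7, a member of a family of near-identical inflammasome sensor genes, had 0, 1 and 0 counts in gKO and 95, 41 and 58 in gWT, a ratio of 181 (95% exact interval 32.1 to 7194). Its value is uncertain because reads can be split among its relatives.

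Homeostatic genes, which define resting microglia, were not called as a list (camera adjusted p = 0.434). Of 28 tested members, 1 rose and 0 fell (1 and 0 adjusted over the list alone), with a median log2 fold change of 0.10: Slc2a5, a fructose transporter, from 133 ± 10.5 to 236 ± 9.54 CPM (SD, n = 3 each; log2 fold change 0.83, SE 0.12, edgeR adjusted p = 0.0312). The microglial receptors P2ry12 and Cx3cr1 had log2 fold changes of 0.18 (SE 0.20) and -0.15 (SE 0.24). EdgeR called 0 of 26 genes of disease-associated microglia (median 0.07; 3 at an unadjusted p under 0.05, 1 lower adjusted over the list alone) and DESeq2 1 lower, the smallest p being that of the Wnt inhibitor Dkk2, with a log2 fold change of -2.57 (SE 0.49) and an edgeR adjusted p of 0.0811. EdgeR called 0 members among 37 lysosomal genes (median 0.06), 37 myeloid transcription factors (0.02), 24 antigen presentation genes (0.11), 22 complement and Fc receptor genes (-0.04) or 28 phagocytic genes (-0.02), with 1, 3, 5, 7 and 2 at an unadjusted p under 0.05. DESeq2 called 1 higher myeloid factor and 1 higher antigen presentation gene, and voom with quality weights 3 higher myeloid factors and 2 higher and 2 lower antigen presentation genes. EdgeR without gKO replicate 3 called 5 myeloid factors higher, 1 to 3 genes in each direction in each of the other 4 lists, and 1 higher and 3 lower disease-associated genes. The homeostatic list had 7 higher and 6 lower genes without gKO replicate 3.

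Single members rose by edgeR in the TGF-beta, p53, chemokine receptor and adhesion lists, which camera did not call. They were Tgif1, a corepressor of TGF-beta signalling (log2 fold change 1.35; list of 31, median 0.10; 4 higher and 3 lower adjusted over the list alone), Trp53inp1, a p53 target (1.16; list of 29, median 0.11; 3 higher alone), Ccrl2, a chemokine-binding receptor (1.17; list of 26, median -0.06) and Mmp9 among 34 adhesion and matrix genes (median 0.07). In the glycolysis and hypoxia list, the stress-induced mTOR inhibitor Ddit4 (1.45) and the glucose transporter Slc2a3 (1.11) rose among 29 genes (median -0.06; 2 higher and 1 lower adjusted over the list alone). The TGF-beta, p53, chemokine receptor, adhesion and glycolysis lists had 10, 4, 3, 11 and 6 genes at an unadjusted edgeR p under 0.05. TGF-beta genes moved in both directions. DESeq2 called 2 higher and 3 lower, voom with quality weights 4 and 2, and edgeR without gKO replicate 3 called 8 and 5. Lists with 0 members called by edgeR were cell cycle (median 0.06), cholesterol handling (0.01), oxidative phosphorylation (0.11), ribosomal proteins (0.16), unfolded protein response (-0.01), small RNA machinery (0.05) and chromatin regulators (-0.06), with 2, 3, 0, 0, 4, 0 and 4 genes at an unadjusted p under 0.05. DESeq2 called 1 higher gene in each of the cell cycle, cholesterol and unfolded protein lists, and voom with quality weights 1, 2 and 1. By camera, 5 of the 34 lists were higher and 5 lower, none of them with an estimated correlation, and the smallest adjusted p among the other 24 was 0.217. The median, the mean and the camera direction differed in sign for the TGF-beta, phagocytic, adhesion, disease-associated, antigen presentation, glycolysis, unfolded protein, purinergic and small RNA lists. Without gKO replicate 3, edgeR called 15 ribosomal and 7 oxidative phosphorylation genes lower, and ribosomal proteins (median -0.26, camera adjusted p = 3.23e-06) and oxidative phosphorylation (-0.17, 0.00266) were called lower and chromatin regulators higher (0.11, 0.0179). The opposite call, higher, came without gKO replicate 1 or 2 for ribosomal proteins (medians 0.35 and 0.33, camera adjusted p = 0.00301 and 0.00165) and for oxidative phosphorylation (0.26 and 0.28, 0.0177 and 0.00619), and without gWT replicate 2 for ribosomal proteins (0.21, 0.0463).

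**Figure D2:**
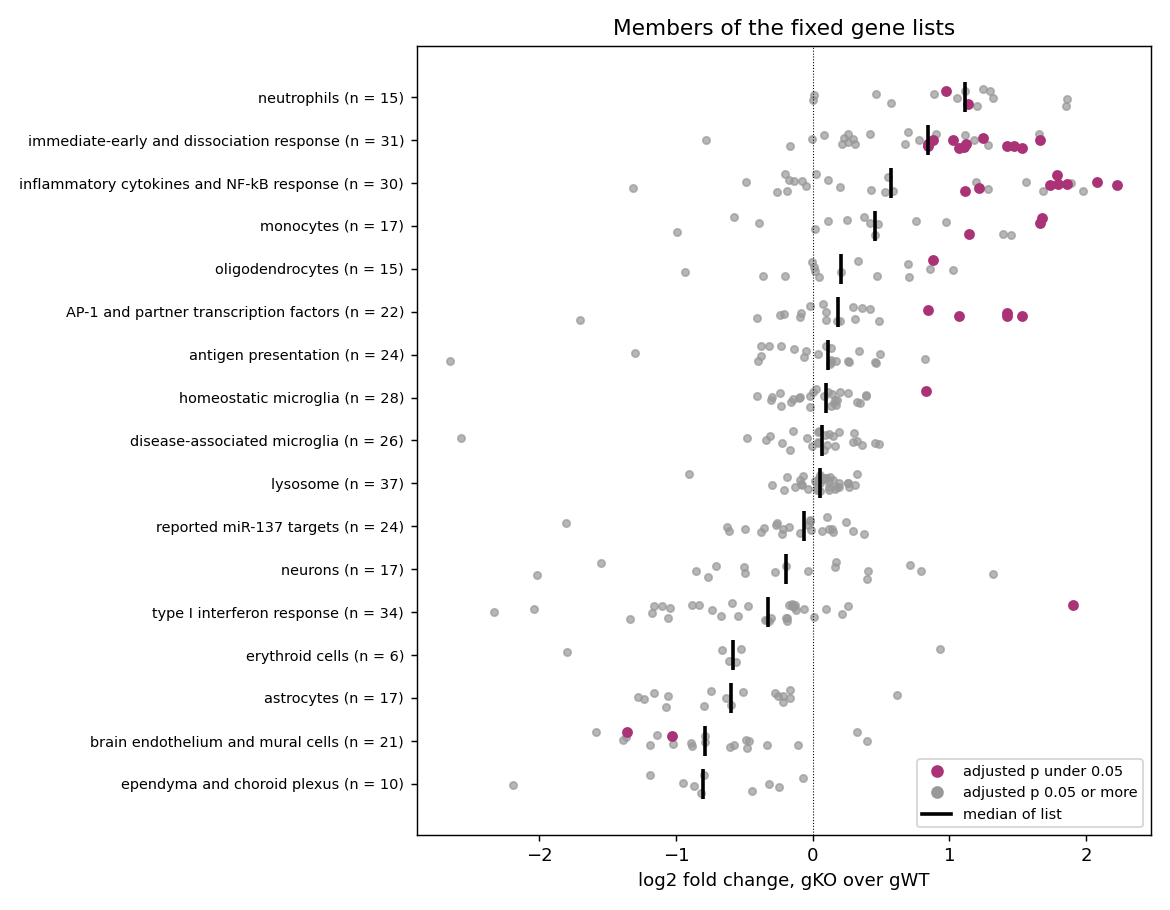
Log2 fold change, gKO over gWT, of each tested member of the called gene lists and of selected other lists, from the edgeR fit to 3 gKO and 3 gWT libraries. Each point is a gene, purple where its adjusted p was under 0.05, the black bar is the median of the list, and n is the number of tested members; neutrophil genes have the highest median (1.11) and ependymal and vascular genes the lowest (-0.80 and -0.79).

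Neither reported targets of miR-137 nor genes with its sites were called as a set. EdgeR called 0 of 24 tested genes reported as its targets (0 adjusted over the list alone, 0 at an unadjusted p under 0.05), with a median log2 fold change of -0.06. DESeq2 and voom also called 0, and edgeR without gKO replicate 3 called 1 lower. The smallest p belonged to Cdc42, a small GTPase, at 0.30 (SE 0.14), and to Ezh2, a histone methyltransferase, at -0.27 (SE 0.17). Among 12908 genes with an annotated 3′ UTR, the 1328 with an AGCAATA site had a median log2 fold change 0.01 above that of genes of like UTR length without one. Of 180 rearrangements of the same bases, 170 gave a difference at least as high (two-sided share 0.133). This rank depended on gKO replicate 3, without which 32 of 180 were as high (two-sided share 0.394). Of the called genes with an annotated 3′ UTR, 4 of 50 higher and 2 of 29 lower genes held a site, against 10.3% of other genes (Fisher's exact test, two-sided p = 0.815 and p = 0.763). The higher genes with a site include Jdp2, Cd83 and Cxcl2, and the lower ones Cxadr and Foxc1; Cd83, Cxadr and Foxc1 fall outside the naming rule and are named after their values were seen.

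The authors' deposited table lists 75 genes as higher and 201 as lower in gKO. Of these, 40 and 31 passed the edgeR test in the same direction, and all 73 and 184 that could be tested had the sign of the authors' fold change. With DESeq2, 72 and 189 passed. The 13 genes called by edgeR but absent from the authors' deposited table, Slc2a5 and Jund among them, all had an absolute log2 fold change below 1. The lists come from these libraries, so the overlap is not independent evidence. Of the listed genes, 66 and 166 passed the edgeR test without gKO replicate 3, and without any other single library at most 5 did.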

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

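Removing the trend with transcript length was added after the data were examined; the other settings were planned. Against 84 called genes (53 higher, 31 lower), DESeq2 called 391 (168 and 223) and voom with quality weights 413 (261 and 152), and they shared 84 and 82 of the original calls. Removing the length trend gave 240 calls (128 and 112), of which 83 were shared, and no filter on low counts gave 47 lower genes. RLE or upper-quartile scaling, plain voom, a minimum of 1 CPM and a fold-change minimum each left the totals within 1.5 times. Leaving out 1 library gave 0 to 1079 calls (0 to 551 higher, 0 to 528 lower), with 1079 without gKO replicate 3, 5 each without gKO replicate 1 or 2, and 0 by edgeR without any 1 gWT library (729 to 921 at an unadjusted p under 0.05), and changed the overlap with the authors' genes from 71 to between 0 and 232. DESeq2 gave an overlap of 261. With fewer libraries the test has fewer degrees of freedom; otherwise the cause was not tested.

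The labels do not say that equal replicate numbers pair the samples, and no pairing was seen. Same-numbered libraries deviated with correlations of 0.0529, -0.0475 and 0.0153, and not every library correlated best with its own number. So few libraries cannot exclude a pairing. With the replicate number as a block, 18 genes were called (11 and 7), all shared with the original calls, and the block changed no call of a gene list.

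With an estimated correlation, 0 of the 10 called lists passed (0 higher, 0 lower); the adjusted p rose to 0.0705 for immediate-early genes, 0.176 for NF-kB genes and 0.185 for vascular genes, since that setting allows members to vary together. fry called 5 lists higher and 3 lower, and leaving out 1 library gave 3 to 7 lower lists, with 3 when gKO replicate 2 was left out. Without gKO replicate 3, 3 lists turned: ribosomal proteins (adjusted p = 3.23e-06) and oxidative phosphorylation (0.00266) to lower, and chromatin regulators (0.0179) to higher. The ribosomal list was instead called higher without gKO replicate 1, gKO replicate 2 or gWT replicate 2 (0.00301, 0.00165 and 0.0463), and oxidative phosphorylation without gKO replicate 1 or 2 (0.0177 and 0.00619). With each library left out in turn, the adjusted p ranged up to 0.850, 0.721 and 0.979 in that order.

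The difference for genes with a miR-137 site lay between -0.0029 and 0.0219 when 1 library was left out, turning negative without gKO replicate 2 (-0.0029, two-sided share 0.0222), against 0.0118 with all 6. It was 0.0180 for the 8-base site and 0.0288 for genes of at least 5 CPM. With totals of 14603884 to 17652976 counts, genes near 1 CPM rest on few counts per library.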

Other observations

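Some genes that glucocorticoids induce were higher in gKO. Fkbp5, a co-chaperone of the glucocorticoid receptor, rose from 207 ± 1.67 to 409 ± 42.6 CPM (SD, n = 3 each; log2 fold change 0.98, edgeR adjusted p = 0.0221), and Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, rose by a log2 fold change of 1.05 (edgeR adjusted p = 0.0294). Both were picked out after their values were seen, with Ddit4 and Hif3a, which respond to the same hormones; Klf9, looked up with them, had a log2 fold change of -0.31 (SE 0.37). A list of other glucocorticoid-induced genes was then fixed before its values were looked up. Of its 15 tested members, 11 were positive and 0 were called by edgeR (6 at an unadjusted p under 0.05), against 2 higher by DESeq2, 3 higher by voom with quality weights and 5 higher by edgeR without gKO replicate 3, with a median log2 fold change of 0.37 (camera p = 0.000502, and p = 0.0205 with an estimated correlation, unadjusted). Members singled out after their values were seen are the metallothionein genes Mt1 (0.93, SE 0.32) and Mt2 (0.86, SE 0.39), the decoy receptor gene Il1r2 (1.34, SE 0.49) and Cdkn1a (0.58, SE 0.14). The 4 negative members were Pdk4 (-0.58), Map3k6 (-0.28), Txnip (-0.07) and Angptl4 (-0.03). The summed level of the list overlapped between the groups (1624 to 1879 CPM in gKO, 1561 to 1682 CPM in gWT), most of it from Txnip, at 1313 CPM on average. A rise of some glucocorticoid-induced genes, not of all, may therefore be present. Whether it reflects the genotype, the state of the mice or the time of collection was not tested.

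Some genes of low counts were detected in one genotype only. Growth hormone, Gh (chromosome 11, 106300271 to 106301865), had 40, 48 and 30 counts in gKO and 0 in each gWT library, at least 42.1-fold higher against a floor of 3 counts over the group, with an edgeR adjusted p of 0.0673. In the other direction, 19 genes had at least 10 counts in every gWT library and 0 in every gKO library. They include the Wnt ligand gene Wnt16 (39, 44 and 13 counts), the transporter gene Abcc6 (39, 27 and 40) and Adamts14, a procollagen-processing protease gene (25, 33 and 26). None of these genes was among the 31 that edgeR called lower, though the authors listed Wnt16, Abcc6 and Adamts14 as lower. The other 18 choices of 3 libraries gave 0 to 3 such genes. The gKO libraries also had fewer genes with a count above 0 (13832 to 14090) than the gWT libraries (15012 to 15277). The lower counts of the 19 genes cannot be told apart from lower detection in gKO. That limit does not cover Gh, which had counts in gKO only and which the authors listed as higher. Gh and the 19 genes were sought after the data were examined.

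Of the tests in the paragraphs that follow, those on homeostatic genes, neutrophil RNA, heat shock genes, other cell types and Y-linked genes and the splits for genes were chosen only after the result was seen, and the removal of the length trend was added after the data were examined.

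The immediate-early and NF-kB lists were both called higher by camera, though not with an estimated correlation. A smaller share of vascular cells would raise microglial genes alike, but the homeostatic list had a median log2 fold change of 0.10 against 0.84 for immediate-early genes. This contrast could hardly have come out otherwise and decides little. The vascular list summed to only 1094 CPM in gWT and 608 CPM in gKO, and TMM scaling removes a shift common to most genes. With the length trend removed, the median of the immediate-early list was still 0.80 (camera adjusted p = 7.38e-18). Neutrophil RNA cannot be told apart: the summed rise of the neutrophil list (419 CPM; 6 of its genes are among those the authors listed) was 6.99% of that of the called immediate-early genes (5997 CPM) and 26.6% of that of the NF-kB list (1573 CPM), and how much early RNA neutrophils hold was not measured. Handling during isolation remains open, because heat shock members had a median of 0.0388, which decides nothing since 2 were positive and 2 negative, and an effect of the genotype remains an untested hypothesis beside it.

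The vascular list was lower by camera, though not with an estimated correlation. The length trend is excluded by a vascular median of -0.77 after its removal (camera adjusted p = 4.25e-08). The neutrophil median of 1.11 (0.58 without gKO replicate 3) argues against a lower share of every cell type other than microglia. That list was not called with an estimated correlation either (camera adjusted p = 0.161). A lower share of several other cell types remains open. The astrocyte, ependymal and erythroid lists were also lower (medians -0.60, -0.80 and -0.59), while the oligodendrocyte median was 0.21. A smaller carry-over of vessel fragments into the gKO libraries is consistent with a second list of endothelial markers, fixed before its values were looked up: 90.0% of 20 genes were negative, with a median of -0.69 (camera p = 2.79e-07, and p = 0.0270 with an estimated correlation, unadjusted). Its 3 most abundant genes moved less or the other way: Eng (250 CPM on average, log2 fold change -0.43), Cd34 (179 CPM, -0.30) and Ecscr (94.5 CPM, 0.28). Of the 21 genes in the original vascular list, 1 is also in another list and 6 are among those the authors listed; the labels name no sort or gate. A lower expression of these genes within vessel cells or a change in the vessels of the mice would look the same and was not tested. No list of fibroblast or meningeal markers was among those tested. These lists therefore do not tie the falls of Foxc2 and of the collagen genes to vessels.

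Xist was lost from gKO while Y-linked genes were present in every library. Female mice alone in gWT are excluded, since the lowest count of a Y-linked gene in a gWT library was 309. RNA of both sexes in gWT and of males in gKO would lower the Y-linked genes in gWT; their median log2 fold change was 0.29 in favour of gKO, with a median SE of 0.21, and their summed levels did not overlap (184 to 216 CPM in gKO, 157 to 166 CPM in gWT; chance gives 10%). Female RNA in gWT would also raise X-linked genes that escape inactivation there, but their median was 0.01 and their sum 934 CPM in gKO against 866 CPM in gWT, so a mixture cannot be told apart. The sex of the mice is not given in the sources used here, and if sexes were mixed, the genotype comparison could include sex differences.

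Flanking DNA of another strain or an effect of the deletion on its neighbours was tested on genes within 10 Mb of Mir137, leaving out Dpyd and Ptbp2. Of 64 genes, 7 had an unadjusted p under 0.05, or 10.9% (exact 95% interval 4.51 to 21.2), against 10.9% of 13258 genes elsewhere (Fisher's exact test, two-sided p = 1.0). The interval, which treats genes as independent, ends just below a doubling of the share, 21.7%. No excess share was seen among these 64 genes. The test leaves out Dpyd and Ptbp2 and could miss an effect on few genes or a small one, so such an effect remains open.

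The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. For genes, the real split called 84 and the highest other 0 with edgeR (111 to 802 genes at an unadjusted p under 0.05), so 1 split was as large. For lists, the real split called 10 and the highest other 10, so 2 splits were as large. The other splits, which mix the genotypes, called 5, 7, 10, 4, 6, 7, 6, 7 and 0 lists. A camera call at the preset correlation of 0.01 therefore does not by itself tie a list to the genotype.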
